A study of Caenorhabditis elegans with 4 samples.

How the data were processed

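RNA was hybridised to 4 two-colour Agilent arrays of C. elegans genes. Per the labels, Cy5 held RNA from an anti-FLAG pull-down of paraformaldehyde-fixed, lysed worms of a strain with FLAG-tagged PAB-1 in AWA, and Cy3 held RNA from whole him-5 worms, on every array. All 4 arrays belong to 1 group, numbered as replicates 1 to 4 in the labels, and no dye-swapped array was used here. Per the labels, poly(A) RNA was labelled by amplification with cyanine nucleotides.

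The deposited files hold spot intensity values from the scanner software, Agilent Feature Extraction 10.5.1.1 per the submitters' processing notes. Per the file headers, these are mean and local median background intensities per channel before normalisation, processed signals after the software's background subtraction and dye normalisation, flags for outlier spots and for signals well above background, and probe coordinates on the ce4 build of the genome. The software's own log10 ratio, also deposited, followed Cy5 over Cy3 of the processed signals (correlation across spots 0.997 to 0.999 per array) and entered no test. No spot was saturated, and 12 to 32 of the 43803 non-control spots per array carried an outlier flag. The software's slope of observed against expected log ratios of the spike-in controls was positive on all 4 arrays (0.77 to 0.89).

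From these intensities, log2 ratios were computed with limma 3.58.1 in R 4.3.3. Mean signals were corrected with normexp (offset 50) against the local median background, and ratios were normalised within each array by loess with control and outlier spots at weight 0. Outlier spots were then left out and spots of a probe averaged. Probes were kept where Cy5 or Cy3 was well above background on at least 3 of 4 arrays, which left 36478 of 43603 probes. A gene with several probes was represented by the probe with the highest mean intensity over both channels. Of the called genes, 3537 had more than 1 kept probe, and 907 of these had at least 1 probe whose ratio had the opposite sign.

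Probes were named through their sequence name, symbol or accession in a RefSeq gene table of the assembly WBcel235, used only for names. In this way 36171 probes (83.0%) took 1 gene and 7432 took none. Of the named probes, 1318 are listed in the files for another gene too, and 751 tested genes rest on such a probe. Coordinates are those of the probe in the files, on ce4, and the files also give where a probe starts in its target sequence; whether it lies in an exon or a UTR was not determined. Of the 4859 kept probes without a gene, 1632 were higher and 913 lower in a limma fit of all kept probes, adjusted among themselves.

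The test was limma's moderated test (lmFit and eBayes, intercept only) of each gene's mean log2 ratio against 0 over the 4 arrays, with Benjamini-Hochberg adjustment over 17940 genes. Errors are its standard errors. Each ratio sets 1 pull-down against 1 lysate, so the spread of the lysates enters the p-values only through the ratios, and the lysate channels of replicates 3 and 4 did not differ beyond spot noise. Where a gene's probe was not well above background in one channel on all 4 arrays, only a bound is given, from the per-channel means after loess and Aquantile normalisation, which is open to dye bias without dye swaps.

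Before the data were examined, 33 gene lists were fixed, and each with at least 5 tested members was tested with camera at a preset correlation of 0.01, adjusted over the 33 lists. None of the 14 lists called in this way was called with an estimated correlation (median estimate 0.22), and the lowest adjusted p was then 0.22. The limma rotation test fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, called 16 lists. Chemoreceptor genes were taken by name pattern and tested with two-sided Fisher's exact tests with 95% intervals against all other tested genes, and by family with adjustment over 20 families. Fisher's test counts genes as independent units, which genes measured on the same arrays are not. Its p-values and intervals therefore do not measure the spread between arrays.

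Genes were named by a rule set before the data were examined. It took the tested AWA markers, the native genes of the transgene parts and srd-1. It also took the 10 highest and 10 lowest locus-named genes that passed the test, had the same sign on all 4 arrays and were well above background in the higher channel on all of them. From each list it took up to 3 called members at either end, and it took the 10 chemoreceptor genes with the highest called ratios. Within that allowance, lists called by camera gave 3 members in the direction of the shift and 1 against it, and other lists 1 at either end. Genes with only a sequence name were counted and not named.

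Simulated intensities with the real genes, backgrounds and spread of each probe's ratio, and 200 genes of the 17940 changed by known folds, were passed through the same steps for this comparison. In the real data 62.1% of genes were called, so the adjustment was stricter in the simulation. The shares called there do not carry over to the real data. Of the genes changed 4-fold, 63.6% were called when higher and 48.5% when lower, of those changed 2-fold 17.6% and 45.5%, and of those changed 1.5-fold 14.7% and 12.1%. The mean log2 estimate of 4-fold higher genes was 1.63, and 1.82 among the brighter genes, so the offset draws ratios of dim genes towards 0. Of unchanged genes 0.02% were called. A list of 40 genes, raised 2-fold in the normalised ratios, was called while 0 of 32 unchanged lists were. Noise was drawn for Cy5 only, independently for each probe, and list genes were drawn at random, so genes of a list were not correlated. The simulation therefore cannot show how often camera at its preset correlation calls unchanged lists of correlated genes.

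Alternatives set before the data were examined changed the background correction, the normalisation, the filter on dim probes, the treatment of outlier spots, the use of several probes, the variance model, the threshold, the set test and its correlation and the background of Fisher's test, and left out each replicate in turn. Chosen after seeing the data were averaging replicates 3 and 4 as 1, removing a trend on probe GC content, using only probes listed for 1 gene, and leaving pseudogene entries out of the chemoreceptor test.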

Results

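RNA from a pull-down aimed at the AWA neurons was compared with RNA of whole animals on 4 two-colour microarrays. AWA is a pair of olfactory neurons of Caenorhabditis elegans that detect volatile attractants such as diacetyl. Each array carried RNA recovered by anti-FLAG pull-down in Cy5 and RNA from a whole-animal lysate in Cy3. The pull-down strain expressed FLAG-tagged PAB-1, the cytoplasmic poly(A)-binding protein, from the promoter of odr-7, a gene of AWA identity, together with the masculinising gene fem-3 from the pan-neuronal rab-3 promoter. The lysate came from a him-5 strain, in which a mutation raises the share of males, and both strains were grown as mixed-stage cultures. The series describes 4 biological replicates of each RNA, all in 1 group here, and every array had the pull-down in Cy5, so dye, strain and culture went with the RNA source throughout. A log2 ratio above 0 means a higher level in the pull-down than in the lysate, relative to the other genes on the array. Of 43803 non-control spots per array, 73.5% to 76.9% were well above background in Cy5 and 81% to 89.1% in Cy3, and the number of arrays limits the precision.

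The 4 arrays were not equally alike. Across genes, which are not independent replicates, the log2 ratios of replicates 1, 3 and 4 correlated at 0.97 to 0.99, while those of replicate 2 correlated with the others at 0.72 to 0.73. The Cy3 lysate channels of replicates 3 and 4 differed by no more than replicate spots of the same probes (F = 1.33 over 24 replicated probes, with F of 6.50 to 14.9 for the other pairs), while their Cy5 pull-down channels differed beyond spot noise (F = 19.8). With these 2 arrays averaged and counted as 1 replicate, an alternative chosen after seeing the data, 3837 genes were higher and 4126 lower, against 5763 and 5370 in the fit of 4 arrays. Replicate 1 was scanned in another session than replicates 2, 3 and 4, and all 4 arrays lay on 1 slide. Within the session that holds 3 arrays, 3954 genes were higher and 4267 lower.

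The first comparison asked which transcripts were higher in the AWA pull-down than in the whole animal. Transcripts of neurons, sperm and pharynx were among the higher genes, and transcripts of the intestine and of detoxification were among the lower ones. Of 17940 genes tested with limma, 5763 were higher and 5370 lower at an adjusted p under 0.05, 3177 of them at least 2-fold higher and 2211 at least 2-fold lower. The ratio had the same sign on all 4 arrays for 5494 of the higher genes and 5322 of the lower genes. A locus name was held by 3291 of the higher and 3236 of the lower genes, and the others had only a sequence name. Tested against a 1.5-fold change instead of 0, 2567 genes were higher and 2357 lower. Left out in turn, the replicates decided part of the higher count, which was 7843 without replicate 2, 3838 without replicate 3 and 3789 without replicate 4, each fit having 3 arrays.

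At the top of the locus-named genes were saposin-like protein genes and a neuropeptide gene. The highest ratio was that of spp-9 (T25C12.2, X:11488021-11488080 on ce4), a saposin-like protein gene, at 8.87 ± 0.16 (SE, n = 4, adjusted p = 1.0e-04). Its probe is also listed for spp-21, which had a probe of its own at 8.24 ± 0.15, and spp-12 stood at 7.83 ± 0.10. The FMRFamide-like neuropeptide gene flp-1 (IV:9145977-9146036) was 93.1-fold higher, with a log2 ratio of 6.54 ± 0.33. Also among the 10 highest were abu-8 at 6.53, fipr-4 at 6.43, fipr-7 at 6.40, fipr-5 at 6.30, the collagen gene col-74 at 6.26 and nspb-6 at 6.26. The probes of fipr-4 and fipr-5 are listed for further fipr genes, so these values cannot be given to single members of the family.

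The 10 lowest locus-named genes held several genes of metabolism and secreted digestion. The acyl-CoA dehydrogenase gene acdh-1 (I:6498745-6498804) was 61.6-fold lower, with a log2 ratio of -5.95 ± 0.74 (SE, n = 4, adjusted p = 0.0023), and of -6.86 without replicate 2. The cytochrome P450 gene cyp-13A7 (II:9805275-9805334) was 46.5-fold lower at -5.54 ± 0.11. Lysozyme genes lys-4 and lys-5 stood at -4.59 and -4.22, and lipase genes lipl-2 and lipl-5 at -4.59 and -4.12. The others were clec-174 at -4.12, fil-1 at -4.11, the alcohol dehydrogenase gene adh-1 at -3.98 and the aspartyl protease gene asp-13 at -3.98.

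Transcripts known from AWA went both ways, with the diacetyl receptor gene highest. The odr-10 gene (C53B7.5, X:6864351-6864410 on ce4) was 17.9-fold higher in the pull-down, with a log2 ratio of 4.16 ± 0.29 (SE, n = 4, adjusted p = 4.4e-04). The TRPV channel gene ocr-1 (V:10768342-10768401) was 7.57-fold higher at 2.92 ± 0.45 (adjusted p = 0.0045), and the transcription factor gene odr-7 (X:12459051-12459110) 2.79-fold higher at 1.48 ± 0.15. The receptor gene str-44 rose by 0.94 ± 0.20, the TRPV channel gene osm-9 by 0.56 ± 0.10 and odr-4, needed for receptor transport to cilia, by 0.44 ± 0.07. The odr-8 gene, which acts in the same transport, was lower at -0.54 ± 0.08, and sra-13 at -0.25 ± 0.07. The lysate signal of str-44 was well above background on 1 of the 4 arrays and the pull-down signal of sra-13 on 3. No call was made for ocr-2 (0.58 ± 0.24, adjusted p = 0.092), gpa-13 (0.23 ± 0.25), gpa-6 (-0.05 ± 0.18) or odr-3 (-0.06 ± 0.08), and gpa-5 was too dim to be tested. With loess replaced by median centring, odr-4 stood at -0.18 and was not called, osm-9 (0.26) and sra-13 (-0.056) were not called either, and str-44 and sra-13 lost their calls when replicate 1, 3 or 4 was left out and with replicates 3 and 4 as 1. Without replicate 2, ocr-2 (0.86, adjusted p = 2.0e-04) and gpa-13 (0.50, adjusted p = 0.0064) were called higher, and with median centring gpa-6 was called lower (-0.74, adjusted p = 0.015).

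**Figure D1:**
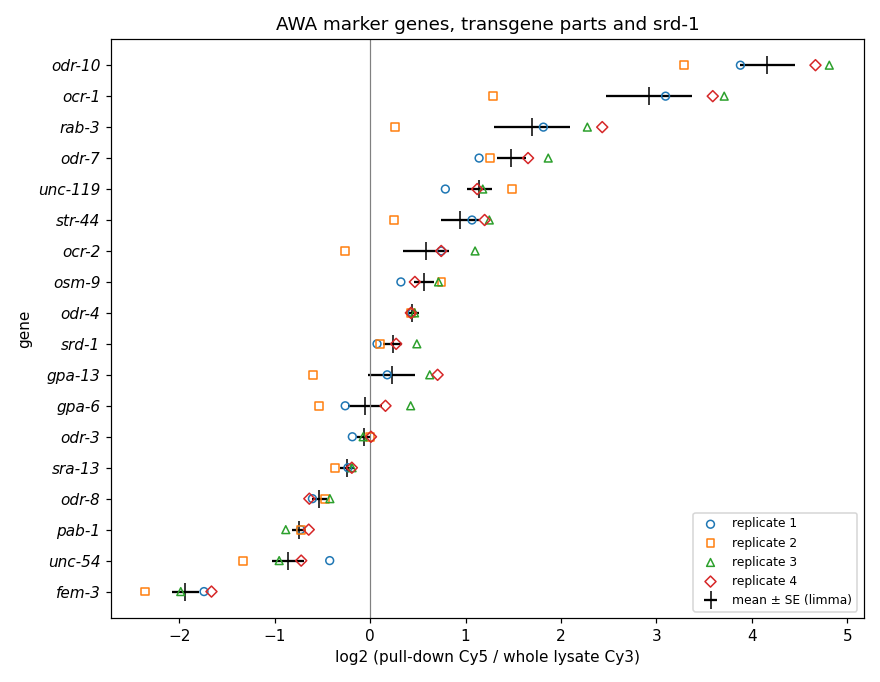
The plot of AWA genes gives the log2 ratio of pull-down Cy5 over whole-lysate Cy3 (x axis) for each gene of the AWA list, each native gene named in the transgenes and srd-1 (y axis), with 1 symbol per array and the limma mean ± SE as a black bar. The odr-10 gene lies highest at 4.16 and fem-3 lowest at -1.94, and replicate 2 lies below the other arrays for ocr-1, rab-3 and str-44.

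As a list of 12 tested genes, the AWA markers had a median log2 ratio of 0.50, with 6 genes higher and 2 lower over all genes and the same counts adjusted over the list alone. The list as a whole was not called by camera (adjusted p = 0.28, and adjusted p = 0.98 with an estimated correlation), while the rotation test, which asks whether its genes move one way and not whether they differ from other genes, gave an adjusted p of 0.049. Of the 12 genes, 10 also belong to another list. The receptor gene srd-1 (F33H1.5, II:10180358-10180737), a sex pheromone receptor of AWA in the literature, had a log2 ratio of 0.23 ± 0.10 (adjusted p = 0.099), positive on 4 of 4 arrays. Its Cy5 signal was well above background on 2 of the 4 arrays. It was called at 0.48 with median centring (adjusted p = 0.016) and at 0.28 without replicate 2 (adjusted p = 0.030).

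Native genes whose parts were used in the transgenes differed in direction. The rab-3 gene stood at 1.70 ± 0.40, odr-7, also an AWA marker, at 1.48 ± 0.15 and unc-119 at 1.14 ± 0.13. On the lower side were pab-1 at -0.75 ± 0.08, unc-54 at -0.86 ± 0.17 and fem-3 at -1.94 ± 0.14 (SE, n = 4). All 6 genes of the list passed the limma test, 3 higher and 3 lower, over all genes and adjusted over the list alone. The list had a camera adjusted p of 0.93 (adjusted p = 0.98 with an estimated correlation). Whether these probes lie in the transcribed parts of the transgenes was not determined, so it is open whether the values include RNA of the transgenes. The unc-119 call was lost with median centring (0.47, adjusted p = 0.13). The rab-3 call was lost without replicate 1, 3 or 4, with replicates 3 and 4 as 1 and with median centring, and with the mean over its probes (0.99, adjusted p = 0.058), as was that of pab-1 (-0.33, adjusted p = 0.14).

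Neuropeptide genes were higher as a group. Of 148 tested, 115 were higher and 5 lower, with a median log2 ratio of 1.96 (camera adjusted p = 6.9e-14, but adjusted p = 0.98 with an estimated correlation). Adjusted over the list alone, 115 were higher and 6 lower. After flp-1, nlp-49 stood at 6.13 ± 0.30 and the insulin-like gene ins-28 at 5.51 ± 0.21, while nlp-20 was lower at -1.46 ± 0.17. Of the 4 probes of nlp-49, 2 went the opposite way.

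Genes of the cilium were higher too, a structure that carries odour receptors in sensory neurons. Of 46 genes of the cilium and intraflagellar transport, 35 were higher and 2 lower, with a median of 0.91 (camera adjusted p = 5.7e-06, adjusted p = 0.98 with an estimated correlation), and 36 and 2 adjusted over the list alone. Examples were bbs-2 at 2.80 ± 0.18, bbs-5 at 2.07 ± 0.13 and the transport gene osm-6 at 1.99 ± 0.14, whereas dyf-7 was lower at -0.74 ± 0.23, with 1 of its 4 probes of the opposite sign and no call without replicate 1, 3 or 4. With the mean over its probes dyf-7 stood at -0.22 (adjusted p = 0.58), and its call was also lost with the GC trend removed (-0.68, adjusted p = 0.053) and with replicates 3 and 4 as 1 (-0.61, adjusted p = 0.11).

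Markers of neurons other than AWA were also higher in the pull-down. Of 24 markers of other amphid sensory neurons, 13 were higher and 3 lower, over all genes and adjusted over the list alone, with a median of 0.87 (camera adjusted p = 0.016, adjusted p = 0.95 with an estimated correlation), and 19 of them also belong to another list. The TGF-beta gene daf-7, known from the ASI neurons, was 22.5-fold higher at 4.49 ± 0.42, nlp-5 stood at 3.76 and nlp-56 at 2.18. The receptor gene sra-6, known from ASH and ASI, was at least 2.46-fold lower, since its pull-down signal was not well above background on any array (adjusted p = 9.1e-04). Without replicate 2 this list was no longer called (median 0.74, adjusted p = 0.053).

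Pan-neuronal genes had a median of 0.57, with 26 of 46 higher and 4 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.0040, adjusted p = 0.95 with an estimated correlation). Among them ric-3, an acetylcholine receptor chaperone, stood at 2.72 ± 0.13, the synaptic vesicle gene sng-1 at 2.70 ± 0.24 and unc-33 at 2.68 ± 0.22, and unc-79 was lower at -0.66. With median centring the median of this list was 0.08 and the call was lost (adjusted p = 0.054). Transmitter markers of other neurons were higher in 14 of 20 genes and lower in 1, over all genes and adjusted over the list alone, with a median of 1.08 (camera adjusted p = 0.015, adjusted p = 0.98 with an estimated correlation). The choline transporter gene cho-1 stood at 3.37 ± 0.40, the dopamine transporter gene dat-1 at 3.06 ± 0.26 and cha-1, choline acetyltransferase, at 2.81 ± 0.30. The lower gene, tdc-1, stood at -0.70, but at 0.32 and without a call as the mean over its 2 probes.

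Touch neuron markers did not shift as a list (12 genes, median 0.07, 2 higher and 3 lower, and 1 and 3 adjusted over the list alone; camera adjusted p = 0.94). Examples were mec-6 at 1.03, not called with median centring (0.47), and mec-18 at -0.85, not called without replicate 1 or 4.

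Male-specific neuron and tail markers were higher in 17 of 21 genes and lower in 1, over all genes and adjusted over the list alone, with a median of 1.83 (camera adjusted p = 2.5e-04, adjusted p = 0.98 with an estimated correlation). The cwp-1 gene, known from male sensory neurons, was 20.4-fold higher at 4.35 ± 0.11, and cil-7 stood at 3.06 ± 0.34. The cwp-2 probe, at 4.91, is also listed for cwp-1. For dmd-3, a gene of male tail development, the pull-down signal was not well above background on any array, giving a level at least 1.21-fold lower (adjusted p = 0.039), a call lost without replicate 1, 3 or 4, with replicates 3 and 4 as 1, with the GC trend removed and with median centring (-0.038).

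Guanylyl cyclases, a list of receptor-type and soluble members, were higher in 18 of 30 genes and lower in 4 (19 and 4 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.016, adjusted p = 0.98 with an estimated correlation). The gcy-15 gene stood at 4.10 ± 0.14, the soluble cyclase gene gcy-33 at 2.1 and gcy-14 at 1.83, with a lysate signal well above background on 1 of the 4 arrays, and gcy-37, also a soluble cyclase gene, at -1.27. Neuropeptide and amine receptor genes were higher in 45 of 123 and lower in 15 (41 and 12 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.015, adjusted p = 0.98 with an estimated correlation). Here npr-29 stood at 2.63 and npr-23 at 2.5, and npr-28 was lower at -1.91. The name pattern of the list also took in 6 tyr genes, named for tyrosinase and not for a receptor, of which tyr-3 stood at 4.13 ± 0.67 (4.96 without replicate 2) and 2 were lower, and without them the median of the list was 0.49. The median of this list was -0.18 in replicate 2 against 0.52 to 0.99 on the other arrays. Its call was lost without replicate 3 (adjusted p = 0.084) and with replicates 3 and 4 as 1 (adjusted p = 0.059), and the rotation test gave an adjusted p of 0.23.

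Other signalling lists were not called by camera. TRP and cyclic nucleotide channels had a median of 0.58 (12 of 21 higher and 4 lower, adjusted p = 0.15), with ocr-1 highest and gtl-1 lowest at -2.14. Voltage-gated and potassium channels had a median of 0.26 (30 of 77 higher and 15 lower, adjusted p = 0.35), with twk-11 at 2.51 and twk-45 at -1.32. Without replicate 2, twk-11 stood at 1.87. For both lists the counts adjusted over the list alone were the same. G protein subunits had a median of 0.11 (7 of 25 higher and 7 lower in both adjustments, adjusted p = 0.88), with egl-30 at 2.25 and gpa-9 at -1.16. The list of RGS, arrestin and receptor kinase genes had a median of 0.20 (5 of 16 higher and 4 lower, 4 and 3 adjusted over the list alone, adjusted p = 0.78), with grk-2 at 2.71 and arr-1 at -1.12.

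The second comparison asked whether chemoreceptor genes were among the transcripts higher in the AWA pull-down. They were not over-represented among the genes called higher: 137 of 654 tested chemoreceptor genes were higher (20.9%), against 5626 of 17286 other genes (32.5%). The odds ratio was 0.55 (interval 0.45 to 0.67, two-sided Fisher's exact test, p = 1.3e-10, with genes counted as independent). Of the 654 entries 98 are pseudogenes in the gene table, 22 of them higher, and with all pseudogenes left out 115 of 556 were higher (odds ratio 0.52, Fisher's exact p = 7.9e-11). They were also under-represented among the lower genes, where 99 were called (odds ratio 0.41, Fisher's exact p = 4.6e-19). Only 40.7% of the 1608 chemoreceptor genes with a probe were bright enough to be tested, against 92.5% of other genes, and those tested had a median log2 intensity of 6.40 against 9.34. The offset draws ratios of such dim genes towards 0, which leaves fewer calls on either side. The low odds ratio therefore does not decide whether chemoreceptor transcripts were in the pull-down. The direction depended on the normalisation: with median centring instead of loess the odds ratio was 1.70 (Fisher's exact p = 8.5e-09), with the scanner's processed signals 1.00 (p = 1.0), and among probes well above background in both channels on all 4 arrays 0.80 (p = 0.12). Some settings moved it further below 1: it was 0.27 with no filter on dim probes, 0.24 at an adjusted p under 0.01, 0.11 with the 1.5-fold test, 0.26 with replicates 3 and 4 as 1, and 0.33, 0.27 and 0.21 without replicates 1, 3 and 4. Others moved it towards 1: it was 0.69 with an offset of 16, 0.64 with the intensity trend and 0.63 with the GC trend removed. It was 0.62 without background correction, 0.61 with the mean over probes and 0.62 without replicate 2.

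After odr-10 the highest called chemoreceptor genes were srsx-6 at 2.08 ± 0.27 (4.22-fold), srg-10 at 1.93 ± 0.44, srb-16 at 1.68 ± 0.20, str-260 at 1.66 ± 0.34, srd-28 at 1.62 ± 0.27, srd-54 at 1.47 ± 0.26, srx-2 at 1.38 ± 0.28 and str-268 at 1.37 ± 0.24 (SE, n = 4). The lysate signals of str-260 and str-268 were well above background on 1 of the 4 arrays, so these ratios rest on a dim channel. The name pattern of the list also took in src-1, at 3.22, which encodes a Src-type tyrosine kinase and no receptor. The srd-28 probe is also listed for srd-27, the call of srg-10 was lost without replicate 1, 3 or 4, that of str-260 without replicate 1 or 4 and that of srx-2 without replicate 4, and srg-10 and str-260 were not called with replicates 3 and 4 as 1. In all, 21 chemoreceptor entries were at least 2-fold higher and 11 at least 2-fold lower. Of 20 families with at least 5 tested members, srh (18 of 100 higher, odds ratio 0.46) and str (17 of 94 higher, odds ratio 0.46) held fewer higher genes than the rest of the array (adjusted p = 0.027 for each). Both also held few lower genes (12 of srh and 16 of str, against 30.5% of genes other than chemoreceptors), with medians of 0.05 and -0.004. With median centring their medians lay 0.56 and 0.54 above that of all genes. No family passed on the higher side, where srb (3 of 6, odds ratio 2.11), srsx (10 of 21, 1.92) and srd (14 of 39, 1.18) had the larger shares (adjusted p = 0.52, 0.32 and 0.68). The median of the chemoreceptor list was 0.02 (camera adjusted p = 0.88), with 82 higher and 74 lower adjusted over the list alone, and with median centring it was 0.22 and called (adjusted p = 9.5e-11).

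Sperm genes were higher as a group, with a median of 2.28. Of 79 tested, 65 were higher and 0 lower, over all genes and adjusted over the list alone (camera adjusted p = 1.1e-07, adjusted p = 0.98 with an estimated correlation, and adjusted p = 0.058 with the rotation test). Examples were nspd-3 at 4.15 ± 0.49, the sperm-specific family P gene ssp-16 at 3.84 ± 0.50 and nspd-5 at 3.75 ± 0.51. The list median was 0.50 in replicate 2 and 2.82 to 2.92 on the other arrays, and without replicate 2 it was 2.88, with nspd-3 at 4.76, ssp-16 at 4.46 and nspd-5 at 4.38. For 16 of these genes the probe is also listed for another gene.

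Pharynx genes were higher in 16 of 20 and lower in 1, with a median of 1.97 (camera adjusted p = 1.6e-05, adjusted p = 0.95 with an estimated correlation), and in 17 and 1 adjusted over the list alone. The pharyngeal gland gene phat-4 (V:4130808-4130867) was 67.8-fold higher at 6.08 ± 0.10, phat-5 stood at 4.68 ± 0.51 and the pharyngeal troponin C gene tnc-2 at 4.67 ± 0.10, and lys-8 was lower at -1.48. Without replicate 2 phat-5 stood at 4.05, and with the scanner's processed signals the list median was 2.66.

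Intestine genes were lower as a group. Of 48 tested, 36 were lower and 6 higher, over all genes and adjusted over the list alone, with a median of -1.39 (camera adjusted p = 3.0e-07, adjusted p = 0.95 with an estimated correlation). After acdh-1, lys-4 and lys-5 were the lowest, while the desaturase gene fat-5 was higher at 2.42 ± 0.29. Oxidative and xenobiotic stress genes were lower in 72 of 131 and higher in 14 (73 and 14 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 1.7e-06, adjusted p = 0.22 with an estimated correlation). Besides cyp-13A7, cyp-37B1 stood at -3.57 ± 0.10 and cyp-13A4 at -3.19 ± 0.32, the latter on a probe also listed for cyp-13A5, and cyp-33B1 was higher at 2.29 ± 0.37.

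Female germline and oocyte genes were lower in 32 of 60 and higher in 10, over all genes and adjusted over the list alone, with a median of -0.45 (camera adjusted p = 0.0067, adjusted p = 0.98 with an estimated correlation). The perm-4 gene stood at -1.98 ± 0.10, the oocyte maturation gene oma-1 at -1.68 ± 0.10 and the P granule gene pgl-3 at -1.63 ± 0.14, and skr-7 was higher at 1.96.

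**Figure D2:**
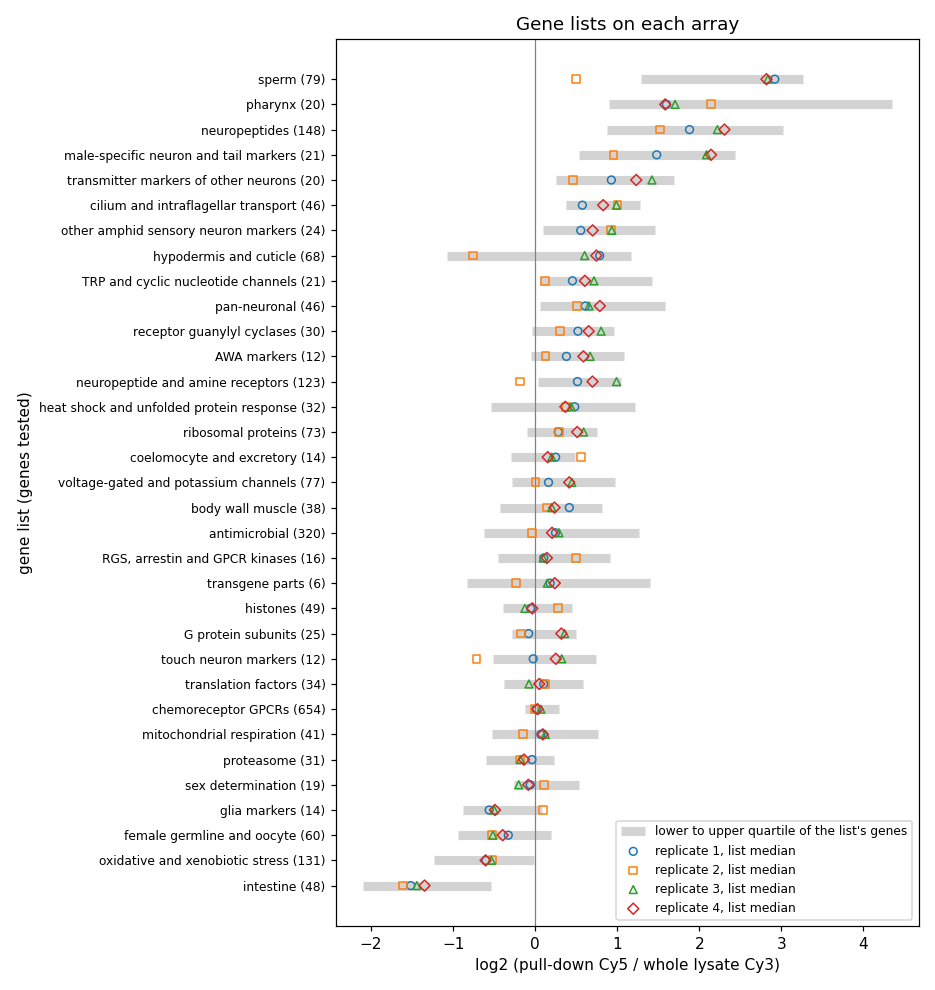
The plot of gene lists gives, for each of the 33 lists (y axis, with the number of genes tested), the median log2 ratio of pull-down Cy5 over whole-lysate Cy3 on each array as 1 symbol per replicate (x axis), over a grey bar that spans the lower to the upper quartile of the list's genes in the 4-array fit. The sperm list has a median of 2.28 and the intestine list one of -1.39, and replicate 2 lies apart for sperm at 0.50.

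Other tissue lists were not called by camera. Body wall muscle genes had a median of 0.21 (16 of 38 higher and 10 lower, adjusted p = 0.55), with the basement membrane gene unc-52 at 2.13 and the myosin gene myo-3 at -0.90. Glia markers had a median of -0.37 (3 of 14 higher and 5 lower, adjusted p = 0.34), with vap-1 at 1.85 and dyf-4 at -1.60. Coelomocyte and excretory genes had a median of 0.40 (4 of 14 higher and 4 lower, adjusted p = 0.77), with lgc-26 at 1.25 and sulp-5 at -1.40. Hypodermis and cuticle genes had a median of 0.59 (25 of 68 higher and 19 lower, adjusted p = 0.55), with dpy-17 at 4.30 and the collagen gene col-93 at -3.57. For these 4 lists the counts adjusted over the list alone were the same. The cuticle list had a median of -0.76 in replicate 2 and of 0.60 to 0.79 on the other arrays, and dpy-17 stood at 3.68 without replicate 2.

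Ribosomal protein genes were higher in 43 of 73 and lower in 12 (45 and 12 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.015, adjusted p = 0.98 with an estimated correlation). The rpl-41.1 gene stood at 1.95, rps-29 at 1.56 and rpl-29 at 1.53, and rpl-3 was lower at -2.46. This call was lost with the scanner's processed signals (median 0.22, adjusted p = 0.29) and with the probe GC trend removed (0.24, adjusted p = 0.19).

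No shift was called by camera for translation factors (median 0.04, 14 of 34 higher and 9 lower), histones (0.12, 14 of 49 higher and 14 lower), mitochondrial respiration (0.01, 16 of 41 higher and 14 lower), the proteasome (-0.10, 8 of 31 higher and 13 lower), heat shock and unfolded protein genes (0.42, 16 of 32 higher and 7 lower), antimicrobial genes (0.20, 125 of 320 higher and 95 lower) or sex determination genes (-0.11, 5 of 19 higher and 4 lower). The camera adjusted p of these 7 lists lay between 0.21 and 0.94. Adjusted over the list alone, the counts higher and lower were 14 and 9 for translation factors, 14 and 10 for histones, 16 and 14 for mitochondrial respiration, 9 and 13 for the proteasome, 17 and 9 for heat shock genes, 128 and 98 for antimicrobial genes and 3 and 2 for sex determination genes. Single members still changed, such as ifg-1 at 2.52, ucr-11 at 1.96, the small heat shock gene hsp-12.2 at 4.06 and tra-1, a regulator of sexual fate, at 1.80 with 1 of its 3 probes of the opposite sign, and on the lower side lpd-6 at -1.93 and dnj-13 at -2.06. The probe for rpn-13, at -2.14, is also listed for let-767, and with probes listed for 1 gene alone rpn-13 stood at 0.43 and was called higher (adjusted p = 0.0095).

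Median centring in place of loess, which sets no intensity-dependent dye trend to 0, moved the median of all genes from 0.07 to -0.32 and the share of calls that were higher from 51.8% to 30.3%, with 3507 genes higher and 8058 lower. It moved 80 of the 120 called genes taken by the naming rule by over 1.5-fold, and the scanner's processed signals moved 34. Medians of called lists that moved by over 1.5-fold with median centring were 0.30 for the cilium, 0.44 for transmitter markers, 1.15 for male neuron markers, 1.32 for neuropeptides and -1.12 for xenobiotic stress. With the processed signals the median was 1.98 for other amphid neurons and 1.44 for guanylyl cyclases, and with no filter on dim probes it was 0.21 for other amphid neurons.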

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

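All tests reported here were chosen after the results were seen. A single array lay apart from the other 3, by Dixon's criterion, for 4 of the 33 list medians and for 23 of the 125 named genes. Chance gives about 1 in 20 (5%) for independent values of equal spread. Among all genes with 4 values the share was 21.3%, with replicate 2 the array apart in 93.5% of these cases.

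Replicate 2 was the array apart for all 4 lists. The sperm list had a median of 0.50 there against 2.82 to 2.92 on the other arrays, and the cuticle list -0.76 against 0.60 to 0.79. The glia list had 0.091 against -0.56 to -0.49, and the list of RGS, arrestin and receptor kinase genes 0.50 against 0.10 to 0.14. For 19 named genes replicate 2 also lay apart. It was lower than the others for spp-9 (8.31), fipr-7 (5.96), lipl-2 (-5.34), clec-174 (-5.21), fil-1 (-4.98), vap-1 (0.96), lys-8 (-1.90), fat-5 (1.35), nspd-3 (2.31), ssp-16 (1.97), nspd-5 (1.85), tyr-3 (1.62), ucr-11 (1.23) and cyp-37B1 (-3.85). It was higher for col-74 (7.68), ric-3 (3.14), phat-5 (6.56), dpy-17 (6.17) and arr-1 (-0.54). Replicate 1 lay apart for abu-8 (6.73) and bbs-5 (1.63), replicate 3 for npr-23 (2.29) and replicate 4 for dmd-3 (-0.083).

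For replicate 2, the scan session was argued against, since replicate 1, scanned in a session of its own, correlated at 0.98 across genes with the mean of replicates 3 and 4, and replicate 2, scanned with them, at 0.73. A weaker pull-down would place values between 0 and those of the other arrays. Of 3433 genes for which replicate 2 lay apart and the others shared a sign, 33.2% lay farther from 0 there than on each other array (6.36% of all genes). Dixon's criterion takes at most 5% by chance for independent values of equal spread. Since replicates 1, 3 and 4 correlated at 0.97 to 0.99, this share does not decide. The list of RGS, arrestin and receptor kinase genes also lay farther from 0, and the cuticle list crossed 0. By these lists a weaker pull-down was argued against as the whole cause. It stays open for part of the lists, because of the 6 at least 2-fold from 0 on the other arrays 4 lay nearer 0 in replicate 2 than on each of them, namely sperm (0.50 against a mean of 2.86), neuropeptides (1.52 against 2.14), male neuron markers (0.95 against 1.90) and transmitter markers (0.46 against 1.19), whereas pharynx (2.14 against 1.63) and intestine (-1.61 against -1.44) lay farther. The AWA marker list, below the 2-fold cut, had a median of 0.13 in replicate 2 and of 0.38 to 0.67 on the other arrays. Its genes odr-10, ocr-1, str-44, ocr-2, gpa-13, gpa-6 and sra-13 were lower in replicate 2 than on each other array. Examples were odr-10 at 3.29 against 3.88 to 4.81 and str-44 at 0.25 against 1.07 to 1.25. Of these genes, odr-10, ocr-1 and str-44 stayed above 0, ocr-2 and gpa-13 fell below 0, and sra-13 lay farther from 0. Only osm-9 was higher than on each other array, at 0.75 against 0.32 to 0.72. The odr-3, odr-4, odr-7 and odr-8 genes lay within the range of the other arrays. Over spots well above background in both channels, Cy5 of replicate 2 differed from the other arrays by a median absolute deviation of 0.58 to 0.60. Its Cy3 differed from replicates 3 and 4 by only 0.065 and 0.056, against 0.053 between those 2. This argues against the lysate of replicate 2 as the main source. A different mix of stages and sexes in the pull-down culture of replicate 2 stays open as an untested hypothesis. The deviations of the sperm genes (-2.17) and the cuticle genes (-0.87) decide nothing about it, because both lists were picked for lying apart, and stage and sex were not recorded per replicate.

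The sperm, pharynx, neuropeptide and male neuron lists, whose names point away from AWA or beyond it, were higher in the pull-down. Probe position went with the ratio, with a median of 0.53 in the tenth of genes whose probes lie nearest the start of their targets, but over random lists matched on that position and on intensity the 4 lists still had an excess of at least 1.48, and transcript length itself was not measured. Whether the pull-down cultures held another mix of stages and sexes than the reference cultures cannot be told apart from the pull-down itself, because strain and culture went with the channel on every array, and the sperm median of 0.50 in replicate 2 leaves this open. The masculinising fem-3 transgene of the pull-down strain went with the channel as well, so its part in the male neuron list cannot be told apart either. Expression of the genes of these 4 lists in AWA, as the design would have it, was not tested and stays open too. No array held a pull-down from worms without the tagged protein, so RNA recovered without the tag was not measured.

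The intestine list was lower in the pull-down. The body wall muscle median lay above the intestine median by at least 1.58 on each of the 4 arrays (SD of that gap 0.15). An equal loss of every tissue other than AWA would not give this gap by itself. Strain, culture and dye went with the channel on all 4 arrays and could give it together with an equal loss. The gap therefore does not decide, and the intestine list was taken up after it was seen to be low. Probe GC content was argued against as the whole cause, since the intestine median was -1.35 with each array's GC trend removed. Camera still called the list then at its preset correlation, while without that removal the adjusted p was 0.95 with an estimated correlation. A different culture or stage of the 2 strains stays open.

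Of the 8 ways to flip the signs of the 4 arrays, 1, the real one, gave as many genes, with 11133 called in all against at most 0 for the others. So few flips cannot give a share under 0.05.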

How the results depend on the processing

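Averaging replicates 3 and 4, removing the GC trend, using probes listed for 1 gene and leaving out pseudogenes were chosen after seeing the data, and the cause of a change was not tested unless fewer samples or another threshold gives it. Of 120 named genes with a call, at most 17 lost it under an alternative (the 1.5-fold test), besides those whose sign turned. Their ratios moved by over 1.5-fold for 80 genes with median centring, 34 with the processed signals, 13 with the mean over probes and 8 without replicate 2. They also moved so for 7 genes with an offset of 16 and for 2 of 116 with probes listed for 1 gene. Without background correction, with an offset of 16, with scaling between arrays, without the dim filter, with outlier spots kept and with the intensity trend, all counts stayed within 1.5 times. Dim signals limit the chemoreceptor results.

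Higher genes (5763) numbered 3507 with median centring, 3614 at an adjusted p under 0.01, 2567 with the 1.5-fold test, 3837 with replicates 3 and 4 as 1, and 3789 to 7843 with a replicate left out. Lower genes (5370) numbered 8058 with median centring and 2357 with the 1.5-fold test. With median centring 1795 genes were at least 2-fold higher and 5365 at least 2-fold lower, and with the processed signals 3836 were at least 2-fold lower. The chemoreceptor odds ratio (0.55) was 1.70 with median centring, 1.00 with the processed signals and 0.80 with both channels well above background on all arrays, but 0.27 with no filter on dim probes, 0.24 at an adjusted p under 0.01, 0.11 with the 1.5-fold test, 0.26 with replicates 3 and 4 as 1 and 0.52 without pseudogenes, and 0.21 to 0.62 with a replicate left out. It was 0.69 with an offset of 16, 0.64 with the intensity trend, 0.63 with GC removal, 0.62 without background correction and 0.61 with the mean over probes.

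With an estimated correlation 0 lists were called, with an adjusted p of 0.95 (other amphid neurons, pan-neuronal, pharynx, intestine), 0.22 (xenobiotic stress) or 0.98 (cilium, transmitters, male neurons, female germline, sperm, guanylyl cyclases, neuropeptides, neuropeptide and amine receptors, ribosomal proteins). With the rotation test the adjusted p was 0.058 for sperm, 0.23 for neuropeptide and amine receptors and, for lists it newly called, 0.049 for AWA markers, 0.044 for body wall muscle, 0.012 for the proteasome and 0.00066 for heat shock genes. Other calls that changed, by median, were ribosomal proteins with the processed signals (0.22) and with the GC trend removed (0.24), pan-neuronal genes (0.079), chemoreceptors (0.22, now called) and antimicrobial genes (0.13, now called) with median centring, and neuropeptide and amine receptors with replicates 3 and 4 as 1 (0.37). Left out in turn, the replicates gave medians of 0.74 to 0.90 for other amphid neurons (not called without replicate 2) and 0.35 to 0.69 for neuropeptide and amine receptors (not called without replicate 3).

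Directions turned for lists not called over the 4 arrays, by camera's direction, which need not follow the sign of the median. Over the 4 arrays this direction was lower for transgene parts (median 0.20), touch neurons (0.07), mitochondrial respiration (0.01) and sex determination (-0.11). It was higher for the other lists named here. Where transgene parts turned, their median was 0.15 with the processed signals, -0.082 with median centring and 0.33 with the mean over probes. That of mitochondrial respiration was 0.012 with an offset of 16, -0.031 with the processed signals and -0.12 with median centring. Median centring also turned coelomocyte and excretory (-0.43), RGS and arrestin (-0.71), translation factor (-0.34) and histone genes (-0.52). The strict filter turned histones (0.14) and sex determination (0.057), the mean over probes touch neurons (0.066) and translation factors (-0.12), and GC removal histones (0.0059). Leaving out replicate 2 turned touch neurons, RGS and arrestin genes, translation factors, histones and mitochondrial respiration, and leaving out replicate 3 turned sex determination. Over the fits with a replicate left out the medians were 0.0033 to 0.13 for touch neurons, 0.054 to 0.26 for RGS and arrestin genes, 0.034 to 0.11 for translation factors, -0.059 to 0.21 for histones, -0.022 to 0.11 for mitochondrial respiration and -0.11 to -0.0037 for sex determination. The rotation test turned coelomocyte and excretory (adjusted p = 0.51), mitochondrial respiration and sex determination (0.82 each).

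Single genes turned as follows: odr-3 0.026 with the processed signals and 0.13 with median centring, gpa-13 -0.16, ocr-2 -0.30 and odr-4 -0.18 with median centring, tdc-1 0.32 with the mean over probes, rpn-13 0.43 with probes listed for 1 gene, and gpa-6 0.013 with GC removal and -0.21 to 0.11 with a replicate left out. Of these, odr-4 and tdc-1 had calls that were lost and rpn-13 was called on the other side.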

Other observations

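Gene families taken by the stem of their locus name, chosen after the data were seen, gave a second view of the same ratios. Of 173 families with at least 10 tested genes, camera called 22 higher and 13 lower, and with an estimated correlation 0 (lowest adjusted p = 0.96). The called families with the highest medians were nspb (12 of 12 genes higher, median log2 ratio 4.74), the major sperm protein family msp (27 of 27, 3.27), fipr (18 of 24, 2.98), ssp (11 of 12, 2.92), abu (12 of 13, 2.91), the neuropeptide family flp (26 of 31, 2.59) and nssp (71 of 78, 2.38). In replicate 2 the median of nspb was 3.29, that of msp 1.59 and that of ssp 1.01. Of the other families of this size whose names begin with nsp, nspg was called lower (10 of 13 genes lower, median -0.996) and nspc was not called (5 of 18 higher and 2 lower, median 0.083, and -0.43 with median centring). The saposin-like family spp, which holds the gene with the highest ratio, was not called either (10 of 26 higher and 13 lower, median -0.48). The acetylcholine receptor subunit family acr was higher in 15 of 21 genes, with a median of 1.02. The F-box family fbxb was higher in 27 of 96 genes (28.1%), no larger a share than among genes other than chemoreceptors (32.5%). Its median stood at 0.56 in all and at 1.72 in replicate 2, and at 0.22 without that replicate. Probes of 6 nspb, 7 fipr, 5 abu, 3 ssp, 7 nspc, 2 spp and 8 msp genes are also listed for another gene.

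On the lower side, the F-box family fbxa was lower in 64.9% of 191 genes and higher in 4.71%, with a median of -0.65 (camera adjusted p = 2.5e-10, adjusted p = 0.96 with an estimated correlation). The bath and math families, named for their MATH domain, were lower in 33 of 42 genes (median -0.85) and 19 of 35 genes (-0.54). The pals family, known from the response to intracellular pathogens, was lower in 19 of 30 genes (-0.63), the cytochrome P450 family cyp in 46 of 77 (-0.58), the nuclear receptor family nhr in 44.9% of 234 (-0.26), the lysozyme family lys in 7 of 10 (-1.23) and the aspartyl protease family asp in 10 of 16 (-1.09). The medians of all families named here other than nspc, higher or lower, kept their sign with the processed signals, median centring and scaling between arrays, also relative to the median of all genes, which median centring moved by over 0.1. Their sizes moved more: with the processed signals the median was 3.92 for abu, 3.73 for fipr, 5.44 for nspb, -1.46 for math, -1.43 for fbxa, -1.45 for pals, -1.35 for cyp and -1.86 for asp, and with median centring it was 3.85 for nspb, 1.96 for ssp, 1.66 for flp, 1.60 for nssp, 0.41 for acr, -0.96 for nhr and -1.19 for cyp. Without replicate 2 it was 3.63 for ssp and 3.62 for abu.

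The 320 spike-in control spots, which entered no test, had a median Cy5 over Cy3 before normalisation that was 12.8 to 30.8 times that of the gene probes, highest in replicate 1.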
